A study of Mus musculus with 6 samples.

How the data were processed

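Forebrains of mouse embryos at embryonic day 15.5 were measured by RNA sequencing, with 3 control (wild-type) and 3 mutant (Dyrk1a<DlxCre/+>) libraries, 1 per embryo as far as the labels say. The labels do not say whether the embryos came from separate litters, so p-values of single genes measure the spread between these samples. List p-values of limma's camera with a preset correlation assume that genes of a list vary almost independently. They do not measure how far a whole list varies between samples. Per the labels' protocols, RNA was extracted with Trizol and an RNeasy kit and libraries were made with a TruSeq Stranded Total RNA kit with Ribo-Zero Gold. That kit removes ribosomal RNA and keeps RNA without a poly(A) tail, and dUTP marked the strand. The labels also call the molecule polyA RNA; the counts hold abundant RNAs without a poly(A) tail, with Rn7sk between 1.84% and 2.82% of all counts per library. Sequencing was single-end on an Illumina HiSeq instrument. Per the submitters' processing notes and design text, bcl2fastq 2.17.1.14, HISAT2 on mouse GRCm38 release 93, SAMtools 1.9 and HTSeq 0.9.1 were used, and differential expression was computed with FCROS, a method that ranks fold changes. The version of HISAT2 and the strand setting of the counting are not given in the sources used here.

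The values deposited by the authors are raw read counts per gene, whole numbers with 1 column per library and no normalization. The table has 33084 genes, of which 2034 have 0 counts in every library. No row lacked a gene identifier and no column belonged to another series. Gene symbols, coordinates, GC content and transcript length came from GENCODE M21 on GRCm38, the build the authors used, which gave a symbol for 32888 of the identifiers. Genes without a symbol are shown by identifier. HTSeq's default mode leaves out reads that fit several genes equally, but the mode used is not given in the sources used here, so counts of overlapping genes, near-identical copies and antisense partners are uncertain. Among named genes this holds, besides those marked where they appear, for Malat1, Sp9, Nefl, Cdc20, Cdkn1c, Lhx5, Foxb1, Rps4l, Tmem181b-ps and Ttc3, which overlap tested genes on the opposite strand. It also holds for Abhd17a, Ppp1r3f, Sox2, Ntn1, Ddx3y and Ttc3, which overlap tested genes on their own strand.

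Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes were kept by filterByExpr with a count minimum of 10 and a minimum total of 15, which left 19616 genes. Library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood F test with robust estimation, control against mutant, with no covariate, Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are mutant over control. CPM values are scaled by TMM, and log2 CPM values per library used a prior count of 2. The common biological coefficient of variation was 0.135. Standard errors were taken from the fold change and its F statistic, and 95% intervals from the matching t quantile at the fitted degrees of freedom (median 8.8). The median standard error was 0.16 log2 units over all tested genes. Dyrk1a was also compared by a two-sided exact permutation test of CPM.

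Before the data were examined, 38 gene lists were fixed, 34 written out as symbols and the others by symbol pattern. They cover the GABAergic, striatal and cortical lineages, progenitors, cell cycle, neuronal maturation, DYRK1A partners, signalling and stress pathways, and markers of other cell types and neighbouring tissues. The pattern lists are clustered protocadherins, mitochondrially encoded genes, cytoplasmic ribosomal proteins without pseudogenes, Rps6k kinases, Rps19bp1 and Rpl7l1, and replication-dependent histones, which by its pattern also took in H1f0, H1fx and the pseudogene Hist3h2bb-ps. The pattern of the ribosomal list was fixed before, but these exclusions, 26 tested genes, were made with the data open, and those of Rps19bp1 and Rpl7l1 after a first list test had been seen. By the pattern as fixed, 90 of 108 tested members lay above 0 with a median of 0.12 (adjusted p = 2.06e-08, limma's camera with the preset correlation; 0.853 with an estimated correlation and 0.930 by fry), and 6 lists were called as with the exclusions. Lists with at least 5 tested members (37 of them) were tested with limma's camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the lists. The same test was applied to genes within 5 Mb of Dyrk1a, Dyrk1a left out.

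The rule for named genes was also fixed before the data were examined. It takes Dyrk1a, the genes Dlx1, Dlx2, Dlx5, Dlx6, Gad1 and Gad2, up to 4 members per list with the smallest p, and up to 12 genes per direction past the threshold. Since fewer than 10 genes passed, the rule's fallback applied: 10 genes per direction with the smallest p, a mean of at least 1 CPM, every mutant library on 1 side of every control library, and a symbol that is not that of a predicted gene or pseudogene.

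The self-test drew counts from the real means, library sizes and dispersions of all 19616 genes for control against mutant, with 200 genes changed in each of 5 runs. The changed genes, and the raised list described below, were drawn from genes averaging above 1 CPM. With dispersions from the trend, 41.8% of genes changed 1.5-fold, 85.7% of those changed 2-fold and 98.2% of those changed 3-fold were recovered, and 3.7% of the calls were false. With gene-wise dispersions, which add estimation noise, these were 31.6%, 76.4% and 93.0%, and 8.7% of the calls were false. A list of 40 genes raised 1.3-fold was called by camera with the preset correlation in all 5 runs under both dispersions, and 0 of 100 random lists were called. With an estimated correlation that list was called in 4 of 5 runs with trended and 5 of 5 with gene-wise dispersions. This self-test replaced an earlier one with a single run and gene-wise dispersions. Genes in the self-test vary independently, unlike the real lists.

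Replicates were compared before averaging: between libraries of 1 group the chi-square statistic per degree of freedom was 10.1 or more, so no library was a duplicate of another of its group (control against mutant libraries were not compared this way) and, at totals of 24646616 to 38315004 counts, the spread between embryos exceeded counting noise. Alternatives were DESeq2 size factors, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom without and with sample weights, the replicate number as a block, leaving out each library, leaving out haemoglobin, mitochondrial and ribosomal RNA genes, an adjusted p under 0.1, a minimum log2 fold change of 0.5, and windows of 1 and 20 Mb. A rank ordering of fold changes was written after the FCROS description, with 9 pairwise fold changes, a trim of 0.3 and an error level of 0.05. A term for embryo sex was planned and not fitted, since all 6 libraries showed the male pattern. After seeing the data, 3 alternatives were added: only the 4 libraries of replicates 1 and 2, an additive term for replicate 3, and removal of each library's loess trend (span 0.3) on GC content and transcript length, which 99.5% of tested genes had.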

Results

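RNA was sequenced from the forebrain of 6 mouse embryos at embryonic day 15.5. There were 3 wild-type embryos, called controls here, and 3 embryos of the genotype Dyrk1a<DlxCre/+>, called mutants. In the mutants Dyrk1a is inactivated conditionally within the Dlx5 domain, the territory of the developing GABAergic neurons of the ventral forebrain. DYRK1A is a serine/threonine and tyrosine kinase that acts in cell cycle exit and neuronal development. Each library had 1 column of raw gene counts. The control libraries held 33260333, 24646616 and 38315004 counts for replicates 1, 2 and 3, and the mutant libraries held 28339650, 25360030 and 27261073. All 6 libraries had Y-linked transcripts, with Ddx3y at 47.7 CPM (counts-per-million) or more, and little Xist, at 1.18 CPM or less, so 1 sex was sampled.

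The single comparison of the design asks how inactivating Dyrk1a in the Dlx5 domain alters the forebrain transcriptome. The genotype is written with a wild-type allele (+), so 1 copy is taken to remain in that domain. The controls are labelled wild-type. If they lack the Cre driver and the conditional allele, effects of these cannot be told apart from those of the inactivation. The Dyrk1a count itself differed by less than the spread between embryos. In the whole forebrain, no single gene was separated from the spread between embryos, and Dlx and Gad genes, which mark the targeted lineage, lay within 0.10 log2 units of the controls in the fit of all 6 libraries. Histone and ribosomal protein genes lay higher as groups and clustered protocadherin genes lower, by a test that assumes a small fixed correlation between genes, and these calls ended when the correlation was estimated from the libraries.

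Dyrk1a (ENSMUSG00000022897, GRCm38 chromosome 16, 94570010 to 94695517, forward strand) averaged 177 ± 7.58 CPM in controls and 175 ± 14.6 CPM in mutants (SD, n = 3 each). The controls held 169, 183 and 180 CPM and the mutants 186, 159 and 182 CPM. The log2 fold change, mutant over control, was -0.02 with a standard error of 0.09. Its 95% interval ran from -0.22 to 0.19, or from a change of -14.3% to one of 14.2%. A two-sided exact permutation test over the 20 assignments of 6 libraries gave p = 0.90, where 0.10 is the smallest p it allows. The count covers the whole gene, which overlaps the tested gene Gm15971 on the same strand, so it does not single out the deleted part and cannot check the genotype labels on its own.

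**Figure D1:**
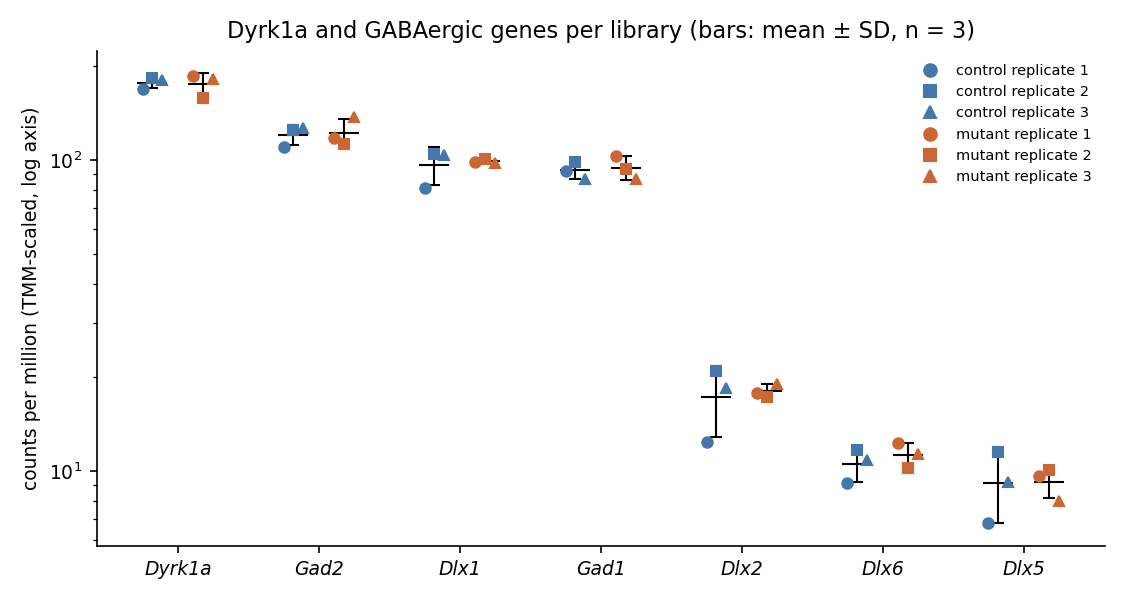
CPM values (log axis) of Dyrk1a and of 6 genes of the GABAergic lineage in each of the 6 libraries. Each point is a library and the bars are the mean ± SD of 3 libraries. Control and mutant points overlap for all 7 genes, with Dyrk1a at 177 CPM in controls and 175 CPM in mutants.

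The genes of the targeted lineage were as close. Dlx1, Dlx2, Dlx5 and Dlx6, homeobox genes that specify ventral forebrain neurons, had log2 fold changes of 0.04 ± 0.11, 0.06 ± 0.18, 0.02 ± 0.20 and 0.10 ± 0.14 (SE). Gad1 and Gad2, which encode the enzymes of GABA synthesis, had 0.03 ± 0.10 and 0.02 ± 0.10. Gad2 averaged 121 ± 9.16 CPM in controls and 122 ± 13.1 CPM in mutants (SD, n = 3 each). None of these 6 genes passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.9999 for each). These values depended on single libraries and weights: over the alternative fits the 6 genes ranged from -0.16 to 0.32, with Dlx2 at -0.13 without control replicate 1, 0.22 without control replicate 2 and 0.32 in limma-voom with sample weights, none past the threshold. Dlx1 and Dlx6 overlap tested genes on the opposite strand, Dlx1as for the former and Dlx6os1 and Dlx6os2 for the latter, and the strand setting of the counting is not given, so their counts could hold reads of these partners. Of the 33 tested genes of the wider GABAergic list, 20 lay above 0 and 13 below, with a median log2 fold change of 0.04 (adjusted p = 0.378, limma's camera with a preset correlation). By the same test that list was called higher without control replicate 2 (median 0.14, adjusted p = 8.8e-04) and with sample weights (median 0.15, adjusted p = 0.0244), and its median was -0.01 without control replicate 1. With an estimated correlation neither call was kept (adjusted p = 0.654 without control replicate 2 and 0.841 with sample weights). Among the smallest p in that list were those of Sst, Sp9 and Npy, at 0.46 ± 0.22, 0.33 ± 0.19 and 0.38 ± 0.23 (SE), none past the threshold.

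Among 19616 tested genes, 0 were higher and 0 lower in mutants at an adjusted p under 0.05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 376 genes, 233 higher and 143 lower, against 981 expected by chance. With fewer small p than chance gives, the lack of calls does not show that no gene changed. DESeq2 also called 0 genes, with 292 at an unadjusted p under 0.05, and limma-voom called 0, with 393. In 626 genes every mutant library lay above every control library and in 725 genes below, together 6.89% of the genes, where chance gives 10%. The unadjusted count depended on single libraries: it was 179 without control replicate 1, 1060 without control replicate 3, 245 without mutant replicate 2 and 689 without mutant replicate 3. It was 845 with a term for the replicate 3 libraries and 1544 with only the 4 libraries of replicates 1 and 2. Limma-voom with sample weights gave 1909, with a smallest adjusted p of 0.364. With the GC content and length trend of each library removed, the count was 394. In simulated data of this size, 76.4% (gene-wise dispersions) and 85.7% (trended dispersions) of genes changed 2-fold were recovered. For genes changed 1.5-fold these shares were 31.6% and 41.8%, so smaller changes of single genes were mostly not detectable here. The simulated changes were in genes averaging above 1 CPM that varied independently, so recovery in the real libraries may be lower. They were also changes of the total in the whole forebrain. A change confined to the Dlx5 domain would appear smaller in these libraries for genes that other cells express too.

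The 10 genes per direction with the smallest p, among genes that met the naming rule, which asks for separated groups, an abundance and a named symbol, did not pass the threshold (adjusted p = 0.9999 for each, edgeR's quasi-likelihood test). All 10 higher and 9 of the 10 lower genes are named here. On the higher side these were Tmem14c, a mitochondrial transporter of haem synthesis, at 0.44 ± 0.11 (log2, SE), and Jund, a subunit of the AP-1 transcription factor, at 0.65 ± 0.17. Jund averaged 55.9 ± 13.9 CPM in controls and 87.8 ± 6.80 CPM in mutants (SD, n = 3 each). Basp1, a membrane protein of growth cones, averaged 194 ± 37.7 and 272 ± 7.66 CPM, a log2 fold change of 0.49 ± 0.13 (SE). The others were the immediate early response gene Ier5l at 0.70 ± 0.18, the orphan nuclear receptor gene Nr2f6 at 0.50 ± 0.13, and the protein phosphatase 1 subunit genes Ppp1r35 at 0.64 ± 0.16 and Ppp1r3f at 0.87 ± 0.23. Abhd17a, a depalmitoylase gene, had 0.34 ± 0.09, the hydrolase gene Abhd8 had 0.41 ± 0.11 and Mrpl34, a mitochondrial ribosomal protein gene, had 0.46 ± 0.12. With the GC content and length trend of each library removed, all 10 values lay nearer to 0: Abhd17a at 0.09, Nr2f6 at 0.21, Jund at 0.36, Ppp1r35 at 0.42 and Ier5l at 0.51 moved by more than 1 SE, and the median of the 10 went from 0.494 to 0.395. Jund, Nr2f6 and Ppp1r3f overlap tested genes on the opposite strand (Gm11175, Ocel1 and Flicr).

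On the lower side, Dsp, which encodes the desmosomal protein desmoplakin, had the smallest p of all genes and averaged 6.52 ± 0.56 CPM in controls and 4.15 ± 0.20 CPM in mutants (SD, n = 3 each), a log2 fold change of -0.65 ± 0.14 (SE). Malat1, an abundant nuclear long non-coding RNA, was at 15177 ± 603 and 12938 ± 898 CPM, or -0.23 ± 0.08. Arhgap11a, a GTPase-activating protein gene, had -0.31 ± 0.09, and Rfx5, a regulator of MHC class II genes, had -0.30 ± 0.09. Anp32b, a histone chaperone gene, had -0.34 ± 0.12. Hif1an, whose product inhibits the hypoxia-inducible factor, had -0.22 ± 0.08, and the moesin gene Msn had -0.27 ± 0.10. The low-count genes Abcb1b and Myom2 had -0.74 ± 0.23 and -0.70 ± 0.25. The 10 higher genes had a median GC content of 61.0% and the 10 lower genes 50.6%, against 48.5% over all tested genes with a sequence match. Their median transcript lengths were 1761.5 and 4789.5 bases, against 3013 over all tested genes. Over 10 classes of transcript length the median log2 fold change was 0.02 in the shortest, 0.05 in the next and -0.05 in the longest.

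The largest difference among the libraries did not follow genotype. The first principal component held 37.4% of the variance and set the replicate 3 libraries of both groups apart from the other 4. Embryonic globin genes, made by primitive red cells, marked the same libraries: Hbb-y stood at 321 CPM in control replicate 3 and 322 CPM in mutant replicate 3, and between 27.8 and 42.5 CPM in the other 4. The proliferating cell genes were 0.68 (control) and 0.66 (mutant) log2 units higher in replicate 3 than in replicates 1 and 2, and the radial glia genes 0.43 and 0.37. The synapse genes were -0.44 and -0.30 and the oligodendrocyte precursor genes -0.61 and -0.61 on the same scale. Mutant replicate 2 stood apart in GC content: its genes of lowest GC content lay at -0.33 and those of highest GC content at 0.24, relative to the control mean.

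**Figure D2:**
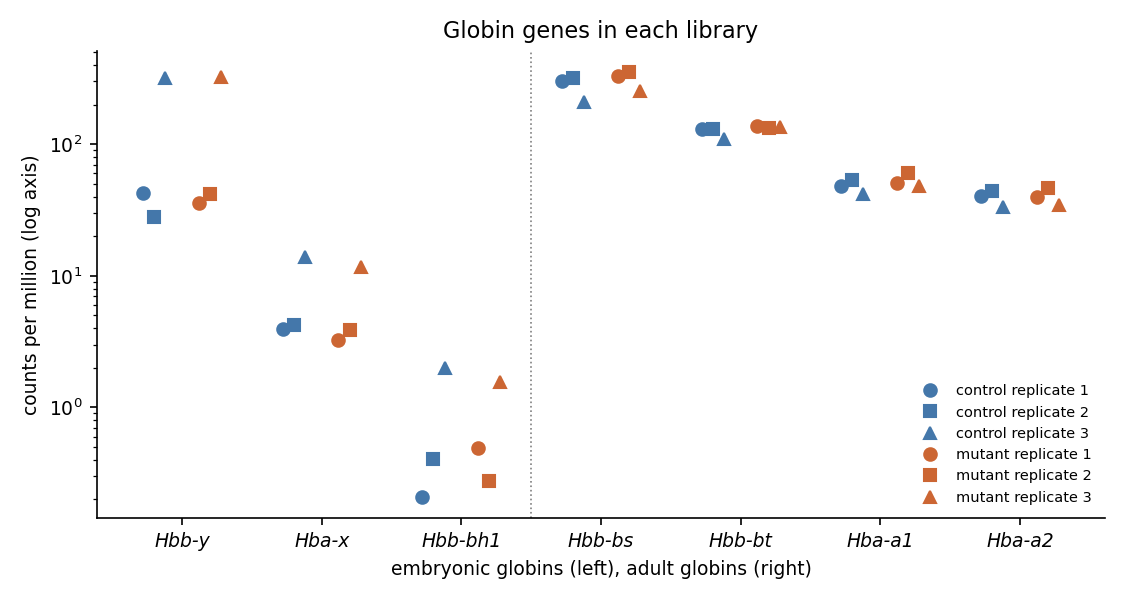
CPM values (log axis) of 3 embryonic and 4 adult globin genes in each library. The replicate 3 libraries of both groups hold the highest Hbb-y values, 321 and 322 CPM, and the adult globins show no such gap.

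**Figure D3:**
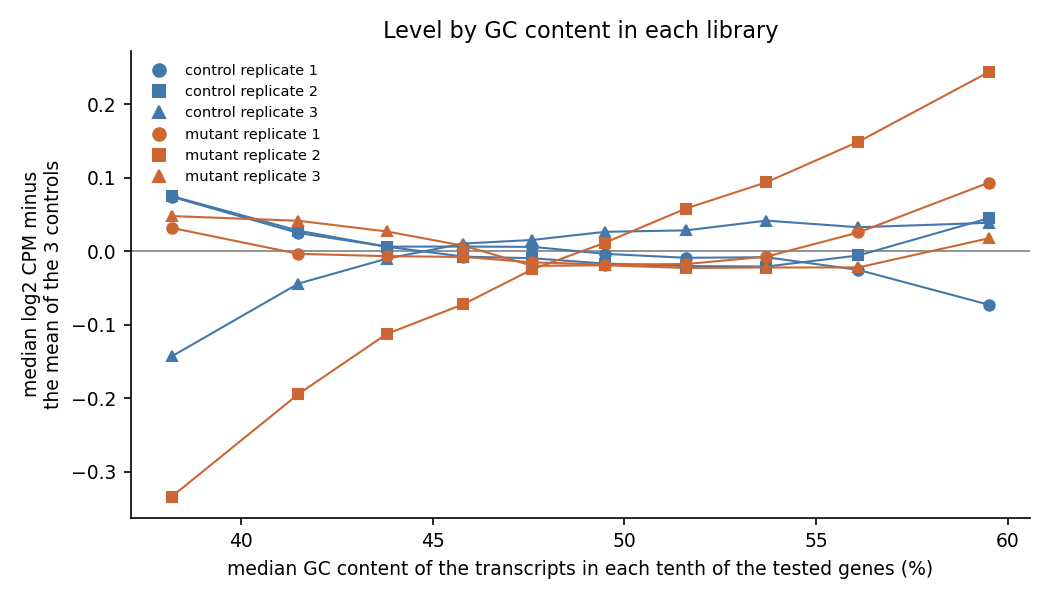
Median log2 CPM of genes in 10 classes of GC content, relative to the mean of the 3 controls, for each library. Mutant replicate 2 climbs from -0.33 at a GC content of 38.2% to 0.24 at 59.5%, and the other 5 libraries stay nearer to 0.

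Of 37 gene lists fixed before the data were examined, with the ribosomal protein list narrowed afterwards, 6 were called by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment, 5 higher and 1 lower in mutants. With an estimated correlation 0 were called (smallest adjusted p = 0.790) and by fry, which asks whether a list's genes move one way on balance, 0 were called (smallest adjusted p = 0.930). No list held a member past the threshold, either over all genes tested or adjusted over the list alone. The number of called lists depended on single libraries: it was 13 without control replicate 3, 14 without mutant replicate 1 and 11 without mutant replicate 2.

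**Figure D4:**
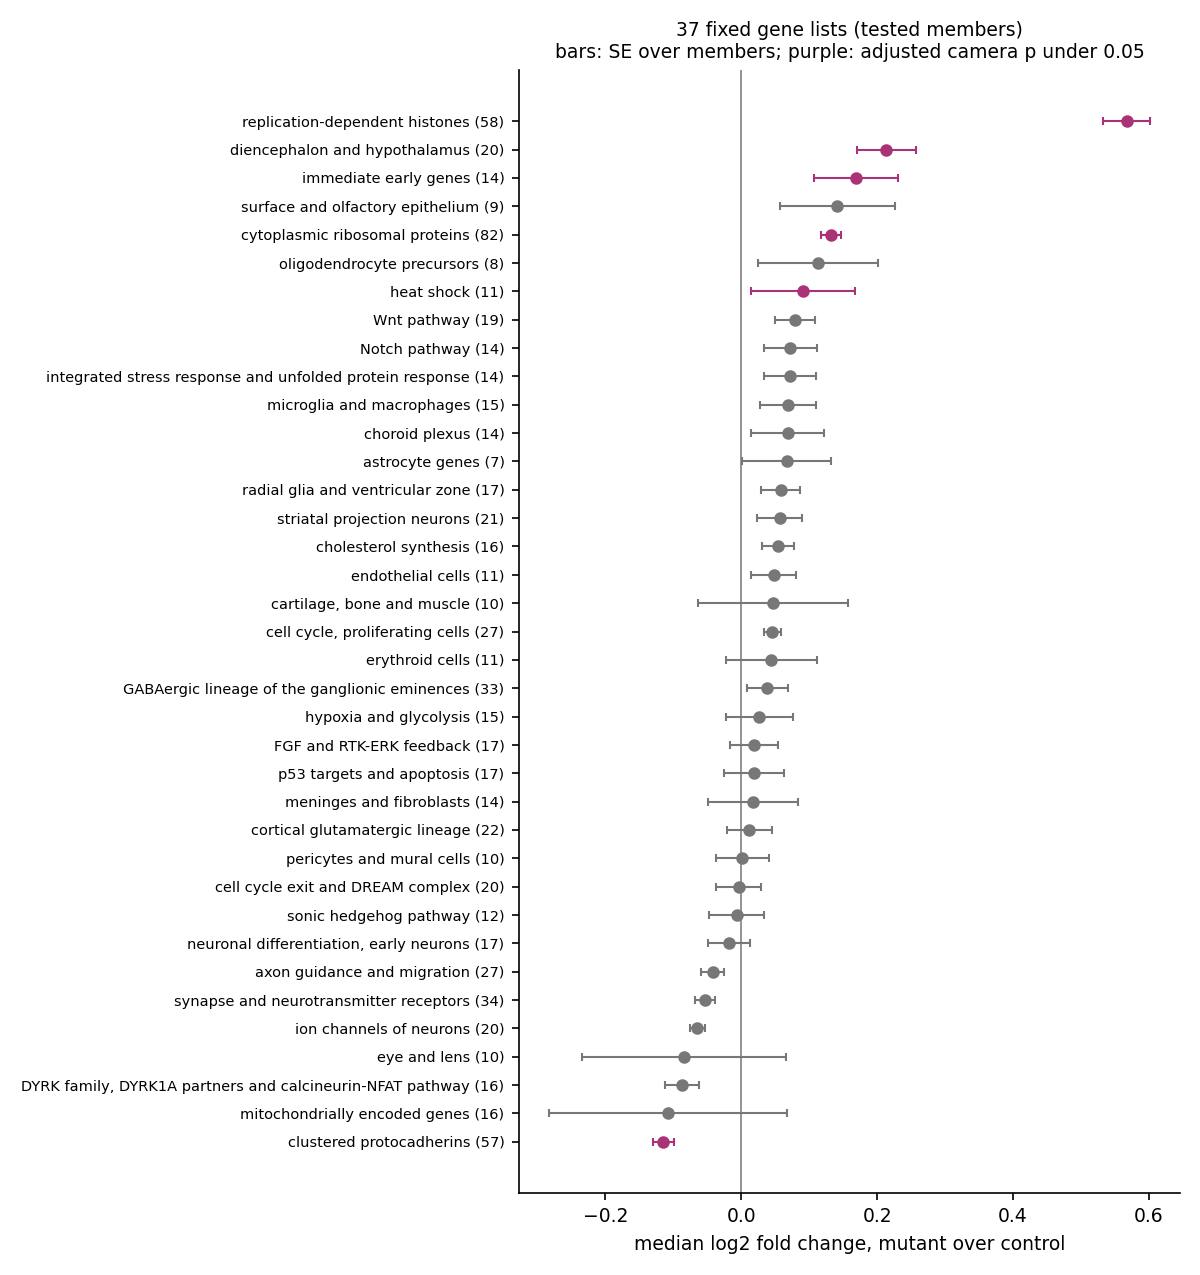
Median log2 fold change, mutant over control, of the 37 tested gene lists with the number of tested members in parentheses. Bars are the standard error of the mean over members, and purple marks the 6 lists called with the preset correlation. The bars treat genes as independent and do not show the spread between libraries. The estimated correlation between genes was 0.78 in the histone list. Replication-dependent histones lie farthest from 0, at 0.57.

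Replication-dependent histone genes, which supply chromatin during S phase, lay higher in mutants as a group: 56 of 58 tested members were above 0, with a median log2 fold change of 0.57 (adjusted p = 1.19e-37, camera with the preset correlation; adjusted p = 0.790 with an estimated correlation). None of the 58 passed alone. The smallest p belonged to Hist1h2af at 0.84 ± 0.25 (SE), the pseudogene Hist3h2bb-ps at 0.62 ± 0.21, Hist3h2ba at 0.54 ± 0.18 and Hist1h1c at 0.45 ± 0.18. Relative to the control mean, the list stood at -0.67, -0.09 and 0.74 in the 3 controls and at 0.36, 0.82 and 0.82 in the 3 mutants. The difference was 0.97 within replicates 1 and 2 and 0.07 within replicate 3. Without control replicate 1 the median was 0.28, and without control replicate 3 it was 1.02. Proliferating cell genes, which differed by replicate, had a median of 0.05 between genotypes, from -0.20 to 0.33 when leaving out 1 library. Many histone genes are near-identical copies, so the split of reads between them is uncertain.

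Genes for cytoplasmic ribosomal proteins also lay higher, with 77 of 82 members above 0 and a median of 0.13 (adjusted p = 2.06e-12, camera with the preset correlation; adjusted p = 0.853 with an estimated correlation). Rps4l, Rplp2, Rpl36 and Rpl41 had the smallest p, at 0.47 ± 0.15, 0.30 ± 0.11, 0.44 ± 0.17 and 0.26 ± 0.13 (SE), and none of the 82 passed alone. The difference was 0.26 within replicates 1 and 2 and -0.10 within replicate 3, so it did not hold in both. Without control replicate 2 the call was lost (median 0.04, adjusted p = 0.0911), and the median was 0.09 without control replicate 1, 0.28 without control replicate 3, 0.20 without mutant replicate 1 and 0.06 without mutant replicate 2. Reads of ribosomal protein genes can be shared with their many pseudogenes.

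Clustered protocadherin genes, which give neurons their surface identity, lay lower, with 48 of 57 members below 0 and a median of -0.11 (adjusted p = 4.03e-05, camera with the preset correlation; adjusted p = 0.853 with an estimated correlation). Pcdhga7, Pcdhga9, Pcdhga6 and Pcdhga1 had the smallest p, at -0.18 ± 0.09, -0.15 ± 0.08, -0.16 ± 0.09 and -0.23 ± 0.15 (SE), and none of the 57 passed alone. The difference was -0.15 within replicates 1 and 2 and -0.07 within replicate 3. The call was lost without control replicate 2 (median -0.06, adjusted p = 0.325) and without mutant replicate 3 (median -0.07, adjusted p = 0.409), and the median was -0.23 without control replicate 3 and -0.18 without mutant replicate 1. Some members share exons and overlap, among them the Pcdhga genes named here, so the separate counts of such members are uncertain. The median GC content was 57.5% for the histone list, 50.9% for the ribosomal protein list and 47.8% for the protocadherin list, with median transcript lengths of 555, 1054 and 4724 bases. These lists also differed in the replicate 3 libraries relative to replicates 1 and 2: protocadherins stood at -0.39 (control) and -0.28 (mutant), along with the synapse and ion channel lists, ribosomal proteins at 0.39 and 0.02 and histones at 1.11 and 0.25. The other called lists stood at -0.22 and -0.14 (immediate early), 0.16 and 0.33 (diencephalon) and 0.27 and 0.15 (heat shock).

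**Figure D5:**
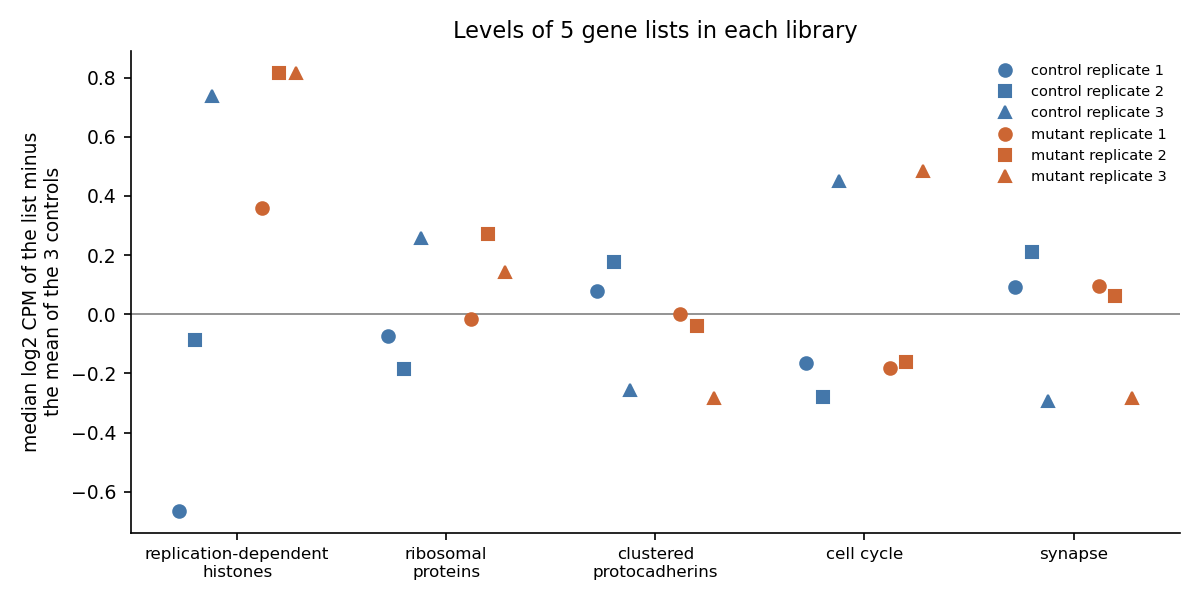
Median log2 CPM of 5 gene lists in each library, relative to the mean of the 3 controls. The histone list separates control replicates 1 and 2 (-0.67 and -0.09) from the mutants (0.36 to 0.82) but not control replicate 3 (0.74), while the cell cycle list follows the replicate 3 libraries of both groups.

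Immediate early genes, induced within minutes of stimulation, were called with 12 of 14 members above 0 and a median of 0.17 (adjusted p = 0.00327, camera with the preset correlation; adjusted p = 0.790 with an estimated correlation). Junb had 0.71 ± 0.21 (SE), from 2.41 ± 0.65 CPM in controls to 3.90 ± 0.24 CPM in mutants (SD, n = 3 each). Jun, Arc and Fos had 0.32 ± 0.13, 0.32 ± 0.16 and 0.49 ± 0.28 (SE), and none of the 14 passed alone. Junb overlaps Prdx2 and Jun overlaps Junos on the opposite strand. The difference was 0.09 within replicates 1 and 2 and 0.15 within replicate 3. The call was lost without control replicate 3 (median 0.16, adjusted p = 0.0695) and with only the 4 libraries of replicates 1 and 2 (median 0.10, adjusted p = 0.0893), and the median was 0.07 without control replicate 1 and 0.37 without control replicate 2.

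Diencephalon and hypothalamus genes, markers of the caudal forebrain, were called with 16 of 20 members above 0 and a median of 0.21 (adjusted p = 0.00338, camera with the preset correlation; adjusted p = 0.790 with an estimated correlation). Irx1, Irx2, Lhx5 and Foxb1 had 0.54 ± 0.23, 0.44 ± 0.22, 0.33 ± 0.17 and 0.35 ± 0.23 (SE), and none of the 20 passed alone. The difference was 0.09 within replicates 1 and 2 and 0.20 within replicate 3. The call was lost without control replicate 1 (median 0.07, adjusted p = 0.116), without mutant replicate 3 (median 0.06, adjusted p = 0.422) and with only the 4 libraries of replicates 1 and 2 (median 0.11, adjusted p = 0.0893), and the median was 0.32 without control replicate 3.

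The heat shock list was called with 9 of 11 members above 0 and a median of 0.09 (adjusted p = 0.0459, camera with the preset correlation; adjusted p = 0.790 with an estimated correlation). Bag3, Hspa1a, Serpinh1 and Hspa8 had 0.46 ± 0.25, 0.82 ± 0.46, 0.20 ± 0.12 and 0.11 ± 0.11 (SE), and none of the 11 passed alone. Serpinh1 is a chaperone of collagen in the endoplasmic reticulum. The difference was 0.15 within replicates 1 and 2 and 0.04 within replicate 3. The call was lost without control replicate 1 (median 0.06, adjusted p = 0.163), control replicate 2 (median 0.03, adjusted p = 0.325) or mutant replicate 3 (median 0.08, adjusted p = 0.241). It was also lost with no filter (median 0.09, adjusted p = 0.0612) and with a filter of 1 CPM in 3 libraries (median 0.09, adjusted p = 0.0703), and the median was 0.20 without control replicate 3 and 0.17 without mutant replicate 1. With the GC content and length trend of each library removed, the immediate early, diencephalon and heat shock calls were all lost (adjusted p = 0.102 for each), while the histone, ribosomal protein and protocadherin calls were not. The immediate early median went from 0.17 ± 0.06 to 0.10 ± 0.05 and the diencephalon median from 0.21 ± 0.04 to 0.12 ± 0.04. The heat shock median went from 0.09 ± 0.08 to 0.08 ± 0.07. The SE given with these medians is that of the mean over members, with genes taken as independent. The heat shock median thus moved by less than that SE while its call ended.

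The remaining 31 lists were not called by camera with the preset correlation, the source of their adjusted p values. Of these, 16 were called in at least 1 of the alternative fits, 11 of them only when leaving out a library. The medians of 21 of the 31 turned their sign when some library was left out, so the side of 0 given for these lists depends on single libraries. Among neuron classes, striatal projection neuron genes had 15 of 21 members above 0 and a median of 0.06 (adjusted p = 0.137), led by Zfp503 at 0.53 ± 0.21 and Tac1 at 0.30 ± 0.16 (SE). Cortical glutamatergic genes had 12 of 22 above 0 and a median of 0.01 (adjusted p = 0.480), led by Neurod2 at 0.31 ± 0.15 and Emx1 at 0.28 ± 0.18. Early neuronal differentiation genes had 7 of 17 above 0 and a median of -0.02 (adjusted p = 0.540), led by Nefl at 0.30 ± 0.15 and Stmn3 at 0.21 ± 0.11. Synapse and receptor genes had 23 of 34 below 0 and a median of -0.05 (adjusted p = 0.269), with Camk2a at -0.23 ± 0.13 and Gria3 at -0.15 ± 0.14. Ion channel genes had 18 of 20 below 0 and a median of -0.06 (adjusted p = 0.164). Axon guidance and migration genes had 19 of 27 below 0 and a median of -0.04 (adjusted p = 0.519), with Ntn1 at 0.25 ± 0.10. The differentiation list's mean and camera direction were positive, against its median.

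Progenitor and cell cycle lists had medians near 0 in the fit of all 6 libraries. Radial glia genes had 12 of 17 above 0 and a median of 0.06 (adjusted p = 0.106), with Sox2, a stem cell transcription factor gene, at 0.40 ± 0.16 (SE). The radial glia median ran from 0.01 to 0.20 when leaving out 1 library. Proliferating cell genes had 23 of 27 above 0 and a median of 0.05 (adjusted p = 0.411), which ran from -0.20 without mutant replicate 3 to 0.33 without control replicate 3, with Cdc20 at 0.20 ± 0.24 (SE). The list of cell cycle exit and the DREAM complex, a repressor that DYRK1A helps to assemble, had 9 of 20 above 0 and a median of -0.004 (adjusted p = 0.913), with camera's direction positive. In it, Cdkn1c, a cyclin-dependent kinase inhibitor gene, had 0.43 ± 0.12, Cdkn2c had 0.27 ± 0.12 and Ccnd2, a cyclin gene, had -0.23 ± 0.10, none past the threshold. Apoptosis and p53 target genes had 9 of 17 above 0 and a median of 0.02 (adjusted p = 0.798), with Bbc3 at 0.35 ± 0.19 and Pmaip1 at -0.53 ± 0.31. That list's mean and camera direction were negative, against its median.

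Signalling lists were not called either. The list of the DYRK family, DYRK1A partners and the calcineurin-NFAT pathway had 13 of 16 members below 0 and a median of -0.09 (adjusted p = 0.137), which was -0.02 without control replicate 2 and -0.04 without mutant replicate 2. Its adaptor gene Dcaf7 had -0.15 ± 0.08 and Ywhae had -0.26 ± 0.15 (SE). Notch genes had 10 of 14 above 0 and a median of 0.07 (adjusted p = 0.137), with Hes6 at 0.26 ± 0.14. Wnt genes had 14 of 19 above 0 and a median of 0.08 (adjusted p = 0.151), with Sp5 at 0.37 ± 0.19. Sonic hedgehog genes had 7 of 12 below 0 and a median of -0.01 (adjusted p = 0.849), with Gas1 at 0.33 ± 0.20. FGF and ERK feedback genes had 9 of 17 above 0 and a median of 0.02 (adjusted p = 0.706), against a negative mean and camera direction and medians of -0.08 to -0.01 when leaving out 1 library, with Dusp4 at 0.16 ± 0.10. Integrated stress and unfolded protein response genes came nearest to a call, with 11 of 14 above 0 and a median of 0.07 (adjusted p = 0.0509), led by Herpud1 at 0.24 ± 0.10. That median ran from 0.001 to 0.18 when leaving out 1 library. Hypoxia and glycolysis genes had a median of 0.03 over 15 members (adjusted p = 0.269), with Adm at 0.62 ± 0.24. Cholesterol synthesis genes had a median of 0.05 over 16 members (adjusted p = 0.442), with Dhcr7 at -0.20 ± 0.10.

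Markers of other cell types and tissues gave no call apart from the diencephalon list. Microglia and macrophage genes had 12 of 15 above 0 and a median of 0.07 (adjusted p = 0.106), with Fcer1g at 0.39 ± 0.19 and C1qc at 0.32 ± 0.19 (SE). Endothelial genes had a median of 0.05 over 11 members (adjusted p = 0.293), and pericyte genes had 0.002 over 10 members (adjusted p = 0.798), with a mean below 0. Choroid plexus genes had 0.07 over 14 (adjusted p = 0.540), with Ttr at 0.22 ± 0.15. Meningeal and fibroblast genes had 0.02 over 14 (adjusted p = 0.419), with Col1a1 at -0.55 ± 0.35. The Col1a1 value rests on control replicate 1, at 73.4 CPM, against 25.3 to 33.9 CPM in the other libraries. Erythroid genes had 0.04 over 11 (adjusted p = 0.25), with Hbb-bt at 0.13 ± 0.09. Oligodendrocyte precursor genes had 7 of 8 above 0 and a median of 0.11 (adjusted p = 0.151), with Sox10 at 0.69 ± 0.45. Their median lay between 0.07 and 0.30 when leaving out 1 library. Astrocyte genes had 0.07 over 7 (adjusted p = 0.685), with Gja1 at -0.23 ± 0.14. Surface and olfactory epithelium genes had 8 of 9 above 0 and a median of 0.14 (adjusted p = 0.151), with Krt18 at 0.73 ± 0.29. Leaving out 1 library moved that median between 0.01 and 0.31. Eye and lens genes had -0.08 over 10 (adjusted p = 0.540), and cartilage, bone and muscle genes had 0.05 over 10 (adjusted p = 0.585). Mitochondrially encoded genes had a median of -0.11 over 16 (adjusted p = 0.378). The hindbrain and midbrain list had 2 tested members, too few for a test: Th at 0.30 ± 0.17 and Slc6a3 at 0.63 ± 0.65.

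Genes flanking the targeted locus were not called as a group. Within 5 Mb of Dyrk1a on chromosome 16, 36 of 73 tested genes lay above 0 and 37 below, with a median log2 fold change of -8.0e-04 (p = 0.331, camera with the preset correlation, direction positive). Within 1 Mb, camera with the preset correlation gave p = 0.560 for 16 genes with a median of -0.02, direction positive. The 118 genes within 20 Mb had a median of -0.02, and limma's camera with the preset correlation gave p = 0.920. No gene in these windows passed. Ttc3, the most abundant neighbour within 1 Mb, averaged 1489 ± 40.6 CPM in controls and 1464 ± 50.7 CPM in mutants (SD, n = 3 each), and Erg, an endothelial transcription factor gene, had 0.31 ± 0.15 (log2, SE). Both were chosen after their values were seen.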

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

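The fits with only the 4 libraries of replicates 1 and 2, with a term for replicate 3 and with GC content and length trends removed were chosen after seeing the data; the other alternatives were fixed before. The count of 0 changed genes held in 16 of 17 other fits of all genes, which had 179 to 1909 genes at an unadjusted p under 0.05. The exception was the 4 libraries of replicates 1 and 2, with 3 genes, all higher in mutants: Hist1h2ag (log2 fold change 1.10, adjusted p = 0.00342), Pisd-ps1 (0.87, adjusted p = 0.00169) and Tmem181b-ps (0.81, adjusted p = 0.00342) in edgeR's quasi-likelihood test, named after their values were seen. In the fit of all 6 libraries they had 0.68, 0.48 and 0.32. The rank ordering of fold changes, closest to the authors' method, took 1117 genes, 622 higher and 495 lower; it takes the tails of its own ranks, and other splits of the 6 libraries gave between 611 and 1309. Dyrk1a lay between -0.05 and 0.05 in 17 alternatives. The Dlx and Gad genes ranged from -0.16 to 0.32 and changed sign in 12 of 102 alternative values, with 0 past the threshold. Of the 20 genes named by the rule, 0 of 340 alternative values passed the threshold; their signs are no test, since the rule asks for separated groups. Of these values 19 moved by more than 1 SE, and removing GC content and length trends took Abhd17a from 0.34 to 0.09, Nr2f6 from 0.50 to 0.21 and Jund from 0.65 to 0.36. Called lists numbered 3 with GC content and length trends removed, 0 with an estimated correlation, 0 by fry, and 6 to 14 when leaving out 1 library; none of the 16 other fits of the lists gave a call with an estimated correlation or fry. The histone list passed in all 17 alternatives that use the preset correlation, with medians of 0.28 to 1.02. The ribosomal protein list passed in 16, the protocadherin list in 15 and the immediate early list in 14. The diencephalon list passed in 13 and the heat shock list in 11. No median changed sign, but the lists were called in these same libraries, so kept signs and calls are no independent test. The median of genes near Dyrk1a was 0.0063 to 0.0235 when leaving out 1 library, 0.0339 with the 4 libraries and -0.0233 in the window of 20 Mb, with 0 alternatives past the threshold. The cause of these shifts was not tested, except that fewer libraries enter the fits without a library and more genes the wider window.

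With the replicate number as a block, edgeR called 0 genes (765 at an unadjusted p under 0.05), 9 lists were called, Dyrk1a had -0.0178 and the genes near it 0.0066. The numbers were not shown to pair the embryos. Same-numbered control and mutant libraries correlated at 0.241, 0.071 and 0.355 in their deviations from the group means, and control replicate 2 correlated best with mutant replicate 1 (0.348), so not every sample correlated best with its own number. A term for embryo sex could not be fitted, and settings for normalized values did not apply. Depth limits low-count genes such as Fos and Hspa1a, at 0.66 and 0.40 CPM in controls.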

Other observations

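The tests of adult globins, of cell cycle genes against histones and of the Dyrk1a interval, and the fits with GC content and length trends removed and without the replicate 3 libraries, were chosen after results were seen. No biological explanation beyond genotype is named by the design. The tests compare the genotypes, and whether genotype is the source of each difference between the groups stays open.

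The replicate 3 libraries of both genotypes differed from the other 4 in more than proliferation and synapse genes. Relative to replicates 1 and 2, sonic hedgehog genes stood at 0.33 (control) and 0.35 (mutant), Notch genes at 0.32 and 0.28 and Wnt genes at 0.25 and 0.24, while FGF and ERK feedback genes stood at -0.24 and -0.08. Ion channel genes stood at -0.36 and -0.38, striatal projection neuron genes at -0.36 and -0.33 and astrocyte genes at -0.34 and -0.44. The GABAergic and cortical glutamatergic lists differed less, with GABAergic genes at 0.01 and -0.03 and cortical glutamatergic genes at -0.12 and -0.07.

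Embryonic globins were higher in the replicate 3 libraries: in log2 units Hbb-y stood at 3.22 (control) and 3.07 (mutant) above replicates 1 and 2, Hbb-bh1 at 2.51 and 1.88, and Hba-x at 1.76 and 1.68. More blood in this tissue would raise adult globins too, and the median difference of 4 adult globin genes was -0.297 (Hba-a1 and Hba-a2 are near-identical and can share reads). A slightly earlier stage of these embryos is a candidate explanation: it needs more proliferating cell and fewer synapse transcripts in both groups, and the value nearer to 0 of the 2 groups was 0.662 for the former list and -0.295 for the latter. The labels give 1 age for all embryos, and with 1 such library per group a difference of litter or dissection stays open beside stage.

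Histone and ribosomal protein lists were called higher and the protocadherin list lower in mutants, with the preset correlation. All 3 calls end with an estimated correlation (adjusted p = 0.790, 0.853 and 0.853, limma's camera). Removing each library's trend on GC content and length left medians of 0.425, 0.097 and -0.092, all more than 0.5 times the uncorrected ones of 0.57, 0.13 and -0.11, which argues against these trends as the whole cause while they may account for part. Without the replicate 3 libraries the histone median was 0.95. This followed from the differences of 0.97 within replicates 1 and 2 and 0.07 within replicate 3, so that fit is no separate test. It shows only that the difference lay in the libraries of replicates 1 and 2. More cells in S phase would raise the proliferating cell list, whose median was 0.046. That median ran from -0.20 to 0.33 when leaving out 1 library and was 0.04 with the 4 libraries of replicates 1 and 2, where the histone median was 0.95. The value of 0.33 came without control replicate 3, where the histone median was 1.02, so the S phase test depends on single libraries and decides nothing. Other splits of the 6 libraries into 3 and 3 number too few for a share under 0.05: 6 of 10 splits, the real one among them, gave at least as many called lists. The real split gave 6 and the others between 2 and 19, so its number of called lists was no larger than other groupings of these libraries gave. More cells in S phase stay open, as does another factor that moves histone transcripts together between libraries. Control replicates 1 and 3 alone stood at -0.67 and 0.74.

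The Dyrk1a count in mutant libraries was not separated from that in controls (log2 fold change -0.02). Loss of a whole transcript from 1 allele in every cell would give a log2 fold change of -1, and the lower bound of the 95% interval was -0.222. The design limits the inactivation to the Dlx5 domain, so loss in every cell was ruled out beforehand and this bound does not check the labels. If recombined cells lost all reads of 1 allele, that bound would allow them to supply up to 28.5% of the forebrain's Dyrk1a transcripts, so a deletion limited to the Dlx5 domain may go unseen; a deletion of a few exons that leaves the rest of the transcript would also. An exchange of control and mutant libraries cannot be told apart from the labelled order with the gene total, as the upper bound was 0.191 and the interval holds 0.

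For the number of changed genes the splits decide nothing, since the real split gave 0 genes and all 10 splits must then give as many. The highest other gave 2. That split set control replicates 1 and 2 and mutant replicate 1 against the rest and had 3633 genes at an unadjusted p under 0.05, against 376 for the real split, which points to a structure of the samples other than genotype.

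Of the 10 genes named on the higher side, 4 (Jund, Nr2f6, Abhd8 and Mrpl34) lie within 767 kb of chromosome 8, from 70698949 to 71465747. In this stretch, picked because of those genes, 24 of 29 tested genes lay above 0, with a median log2 fold change of 0.13 and a median GC content of 57.3%; with GC content and length trends removed 20 lay above 0 and the median was 0.06. None passed the threshold.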
